A study of Homo sapiens with 8 samples.

How the data were processed

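RNA from HMEC-1 cells was measured on 8 Affymetrix arrays, 4 from untreated cultures and 4 from cultures stimulated with MRP8/MRP14, and each array's group and number came from its title. The series' design text describes independent experiments, so the p-values measure the spread between those experiments. The deposited values are intensity values, 1 MAS5 signal per probe set and array, and MAS5 is named per the submitters' processing notes. Its version and settings are not given in the sources used here. In the values themselves, the mean after trimming 2% of the values at each end was 100 on every array, which is what scaling each array to a common target gives. A signal near the bottom of the range has a large relative error, and the number of arrays limits the precision of every value.

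Names came from a platform annotation table and were checked through Entrez IDs against RefSeq names of the assembly GRCh38.p14, whose coordinates were not used. Of 12625 probe sets, 10961 had 1 gene, 545 had several genes and 1119 were unnamed here. Of the probe sets with 1 gene, 10949 matched a RefSeq gene, and 0 symbols needed an update. No gene was named from a probe set with several genes, and 67 control probe sets were left out. Detection calls and raw probe intensities were not analysed here.

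Signals were tested as log2(signal + 2.55), the offset being the median over arrays of each array's 10th percentile, so fold changes of dim genes are understated. Probe sets were kept where the signal was at or above the array's 40th percentile on at least 4 arrays, which left 7646 probe sets. The probe set with the highest mean log2 signal stood for each gene, giving 5517 genes, of which 1013 had more than 1 probe set. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Fold changes are stimulated over control unless the text says otherwise. Figures were drawn with matplotlib 3.10.9.

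For gene groups, 30 lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry beside it. With an estimated correlation, camera uses only the few degrees of freedom left by the arrays. At the preset one it uses those of the many genes, so the former is stricter even where correlation is low. Of the 782 genes listed, 545 were tested. The lists, the design, the rule for named genes and most alternatives were fixed before the data were examined. By that rule the text names up to 12 genes in each direction past the threshold whose groups did not overlap. Where fewer than 5 passed, it names the 5 with the smallest p in that direction, as values. It also names up to 4 members of each list past the threshold, or else the 2 with the smallest p, then S100A8, S100A9, TLR4 and AGER, and the 3 brightest members of each list of markers of other cell types. Other names were chosen after their values were seen, and the text says so where they appear.

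The labels give both groups the numbers 1 to 4 without saying that a number is one experiment. Deviations from the group means correlated across genes at 0.136 to 0.216 for the 4 pairs of arrays with the same number. Some arrays correlated more with another number, control replicate 1 with MRP8/MRP14 replicate 2 (0.330) and MRP8/MRP14 replicate 4 with control replicate 3 (0.146). By a rule set beforehand, which asks only for more than 0.1 in every pair, the numbers are taken to pair the arrays. Since pairs with different numbers also exceeded 0.1, the rule cannot show that a number is one experiment. The fit without a block stayed the main one, as fixed, and values with the number as a block stand beside results that it changes. Values within the arrays numbered 1 and 2 and within those numbered 3 and 4 are also given, because those arrays parted from each other.

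The procedure was tested on simulated data for this comparison, with 200 of 5517 genes changed in each of 20 draws. It recovered 19.2% of genes changed by 0.5 on the log2 scale, 70.9% of those changed by 1, 89.2% at 1.5 and 95.8% at 2, and 4.5% of its calls were false. The simulated genes varied independently with normal noise. The draws held no correlation between genes, no parting of arrays by number and no outlying array. These shares therefore may not hold for the real arrays. Alternatives covered the block, the scaling, the offset, the filter, the variance model, the probe sets used, the set test and the arrays used. Single measures of arrays were compared with exact two-sided permutation tests over 70 arrangements.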

Results

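HMEC-1 is an established human microvascular endothelial cell line. MRP8 and MRP14 are the S100 proteins S100A8 and S100A9, calcium-binding and zinc-binding proteins that neutrophils and monocytes release as a complex. Cell layers were either untreated or exposed to 200 µg/ml of MRP8/MRP14 for 6 h, and the comparison asks which transcripts differ between them. Each group had 4 arrays, and log2 signals of any pair of the 8 arrays correlated across probe sets at 0.941 to 0.970. Control replicate 4 stood apart. Its ratio of 3 prime to 5 prime ACTB signal, a measure of RNA integrity, was 2.03 against 1.004 to 1.16 on the other arrays, and its median signal was 28.9 against 31.1 to 37.6. The log2 ACTB ratio of stimulated arrays was 0.25 under that of controls without reaching significance (difference -0.25, exact two-sided permutation p = 0.371). For GAPDH the difference was -0.053 (exact two-sided permutation p = 0.743).

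Among 10 tested genes of zinc handling, 3 were lower past the threshold in stimulated cells. SLC30A1, the zinc exporter of the plasma membrane, fell 3.21-fold, from a signal of 272 ± 59.0 to 83.6 ± 22.4 (SD, n = 4 per group; log2 fold change -1.68, SE 0.22, adjusted p = 0.0338). The metallothioneins MT1X and MT1E, small proteins that bind zinc and copper, fell 3.34-fold and 2.12-fold. MT1X went from 90.7 ± 29.98 to 24.6 ± 4.7 (SD, n = 4 per group; log2 fold change -1.74, SE 0.23, adjusted p = 0.0338). MT1E went from 1381 ± 181 to 646 ± 50.7 (SD, n = 4 per group; log2 fold change -1.09, SE 0.14, adjusted p = 0.0338).

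Of the 10 tested members of the metallothionein and zinc list, 9 were lower and 1 was higher, with a mean log2 fold change of -0.67 and a median of -0.53 (camera adjusted p = 2.9e-06). Over all genes 3 members passed. Adjusted over the list alone, 6 lower members passed, the 3 above and MT1H (-0.66), MT1F (-0.61) and MT1B (-0.46), and the zinc importer SLC39A14 passed as higher (0.35). The remaining log2 fold changes were -0.25 for MT2A, -0.24 for MT3 (0.41 by its dimmer probe set) and -0.29 for MTF1, the metal-sensing transcription factor. The genes outside the naming rule here were chosen after their values were seen. A probe set shared by MT1M, MT1G, MT1F and MT1P3 had a signal of 554 ± 119 in controls and 360 ± 74.9 in stimulated cells (SD, n = 4 per group; adjusted p = 0.355 over probe sets). With an estimated correlation the list kept its call (adjusted p = 0.0425), but not when the replicate block was added (adjusted p = 0.450). The block leaves that test even fewer degrees of freedom and 0 lists passed, so it can say little about this list. The list kept its call with fry, without the block (adjusted p = 0.00052) and with it (adjusted p = 0.0139). Within the arrays numbered 1 and 2 the list's mean was -0.64, and within those numbered 3 and 4 it was -0.70.

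The same split gave -1.77 and -1.60 for SLC30A1, -1.88 and -1.61 for MT1X, and -0.96 and -1.21 for MT1E. With the replicate block, 2 genes passed, SLC30A1 (adjusted p = 0.0302) and MYH11 (adjusted p = 0.0144), while MT1E (adjusted p = 0.137) and MT1X (adjusted p = 0.222) did not. Leaving out any 1 of the 8 arrays ended the calls of SLC30A1, MT1X and MT1E, with adjusted p up to 0.222 over all alternatives. Their log2 fold changes then ranged from -1.81 to -1.53, from -1.89 to -1.55 and from -1.17 to -1.01. The probe sets of MT1E, MT1H, MT1F, MT1B and MT3 are of the kind shared within a gene family, so the values of single copies are uncertain. Among probe sets without such suffixes, an alternative chosen after seeing the data, 6 list members were left with a mean of -0.53 (adjusted p = 0.129). There SLC30A1 and MT1X still passed as lower over all genes (each adjusted p = 0.0387), while MT3 (0.41 by its dimmer probe set) and SLC39A14 (0.35) were higher.

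**Figure D1:**
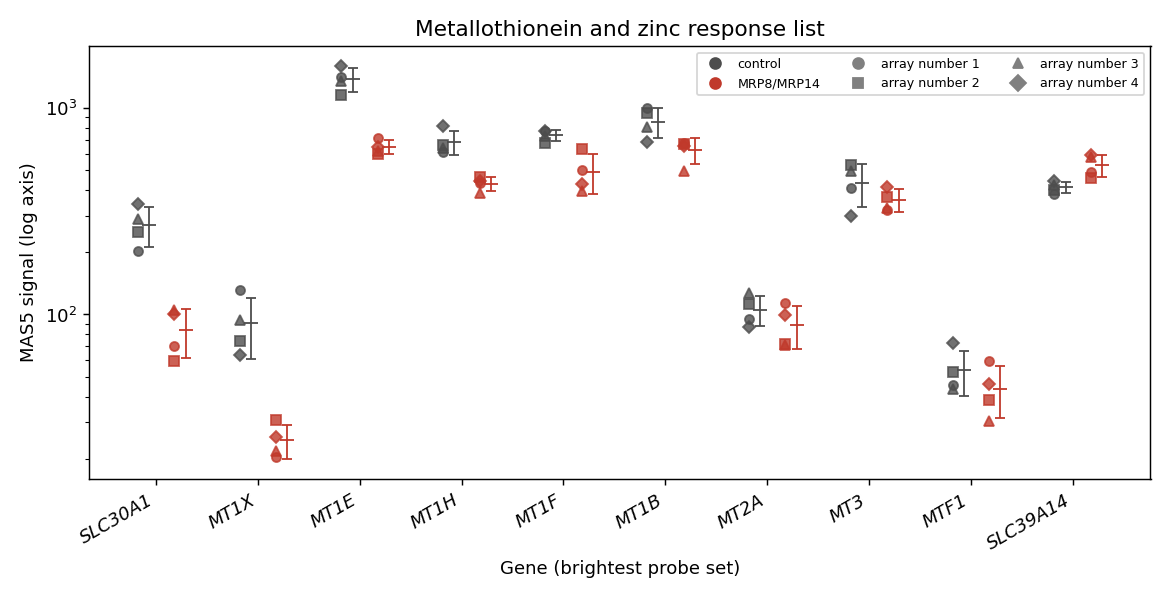
MAS5 signal on a log axis of each of the 10 tested genes of the metallothionein and zinc list, with control arrays in grey and MRP8/MRP14 arrays in red, symbols marking the array number, and a bar giving the mean and SD of the 4 arrays beside them. Signals of SLC30A1, MT1X and MT1E did not overlap between groups, and their log2 fold changes were -1.68, -1.74 and -1.09.

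MYH11, the heavy chain of smooth muscle myosin, was the fourth gene past the threshold and the one with the smallest adjusted p. Its signal was 27.4 ± 6.0 in controls and 5.1 ± 0.74 in stimulated cells (SD, n = 4 per group; log2 fold change -1.95, SE 0.17, adjusted p = 0.00265). This rests on 1 dim probe set, which lay under the 40th percentile on all 4 stimulated arrays. Another of its probe sets differed by -0.61, and the other 3 by 0.022 to 0.18 at signals near the bottom of the range. Without any 1 control array the probe set no longer passed the filter. Without the filter another probe set stood for the gene (adjusted p = 0.753), and with an intensity trend and robust fitting the call ended (adjusted p = 0.0691). Its size depends on the offset, since the stimulated signals lay near the floor, and was -2.40 without the offset and -1.39 with the larger one.

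In all, 4 of 5517 genes passed, each lower and each changed at least 2-fold, and limma called 0 genes higher. ADAM9, a membrane metalloprotease, had the next smallest p among lower genes (log2 fold change -0.82, adjusted p = 0.158). At an unadjusted p under 0.05 there were 396 lower and 183 higher genes, 579 in all, where 276 would be expected by chance on average, and another split of the same arrays gave 940. With the block these counts were 500 and 248. Lower genes made up 68.4% without the block, and 57.3% (310 lower, 231 higher) when each array was centred on its median. Groups did not overlap for 126 higher and 271 lower genes, 7.2% of those tested, where chance gives 2.86%. No gene passed without control replicate 1, 2, 3 or 4, or without the filter on dim probe sets, where 666 genes had an unadjusted p under 0.05. Without any 1 stimulated array, 1 gene passed.

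The chemokine, leukocyte adhesion and NF-kB lists averaged higher signals in stimulated cells, and each was under 0.05 by camera at the preset correlation. None of the 3 calls held with an estimated correlation (adjusted p = 0.135, 0.691 and 0.135 in that order), and no single member passed the threshold over all genes. The neutrophil chemoattractants CXCL1 and CXCL2 measured 130 ± 9.1 and 45.5 ± 5.7 in controls and 249 ± 61.5 and 80.8 ± 11.1 in stimulated cells (SD, n = 4 per group; log2 fold changes 0.89 and 0.79, adjusted p = 0.272 and adjusted p = 0.158). ICAM1 and VCAM1, endothelial receptors to which leukocytes adhere, measured 82.2 ± 9.7 and 57.4 ± 7.2 in controls and 148 ± 19.3 and 106 ± 14.3 after stimulation (SD, n = 4 per group; log2 fold changes 0.82 and 0.85, each adjusted p = 0.158). NFKBIA, the inhibitor of NF-kB that NF-kB itself induces, measured 286 ± 40.3 and 449 ± 33.5 (SD, n = 4 per group; log2 fold change 0.65, adjusted p = 0.272).

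Of 15 chemokines and cytokines tested, 12 were higher and 3 lower (mean log2 fold change 0.34, camera adjusted p = 2.1e-05, but adjusted p = 0.135 with an estimated correlation). Adjusted over the list alone, 5 passed, all higher: CXCL1, CXCL2, CXCL8 (1.10), CCL2 (0.57) and IL6 (0.61), the last 3 chosen after their values were seen. The block added IL32 (0.44), also chosen after its value was seen. The CCL2 probe sets were uneven, at 0.67, 0.57 and 0.022. Of 10 leukocyte adhesion molecules, 6 were higher and 4 lower (mean 0.22, camera adjusted p = 0.0165, but adjusted p = 0.691 with an estimated correlation), and ICAM1 and VCAM1 passed when adjusted over the list alone. This call ended without control replicate 3 (mean 0.13, adjusted p = 0.205) and without MRP8/MRP14 replicate 1 (mean 0.15, adjusted p = 0.107) or 2 (mean 0.15, adjusted p = 0.0866). It also ended without the filter, where the mean was only 0.021 (adjusted p = 0.416). The mean changed little where the call ended with the filter at the 60th percentile (mean 0.20, adjusted p = 0.0836) and among probe sets without suffixes, chosen after seeing the data (mean 0.22, adjusted p = 0.0586). Of 18 NF-kB targets and regulators, 13 were higher and 5 lower (mean 0.19, camera adjusted p = 0.0078, but adjusted p = 0.135 with an estimated correlation).

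Adjusted over that list alone, NFKBIA and NFKB2 (0.94, chosen after its value was seen) were higher, and CFLAR, an inhibitor of caspase-8, was lower (-0.77). The block raised the higher count of this list from 2 to 5. Other CFLAR probe sets differed by 0.0049 and 0.32. Means within the arrays numbered 1 and 2 and within those numbered 3 and 4 were 0.35 and 0.32 for chemokines and cytokines, 0.22 and 0.21 for adhesion molecules, and 0.27 and 0.11 for the NF-kB list. Fry called none of these 3 lists in one direction (adjusted p = 0.0901, 0.421 and 0.0901 in that order), and with the block it called the adhesion list (adjusted p = 0.0223).

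**Figure D2:**
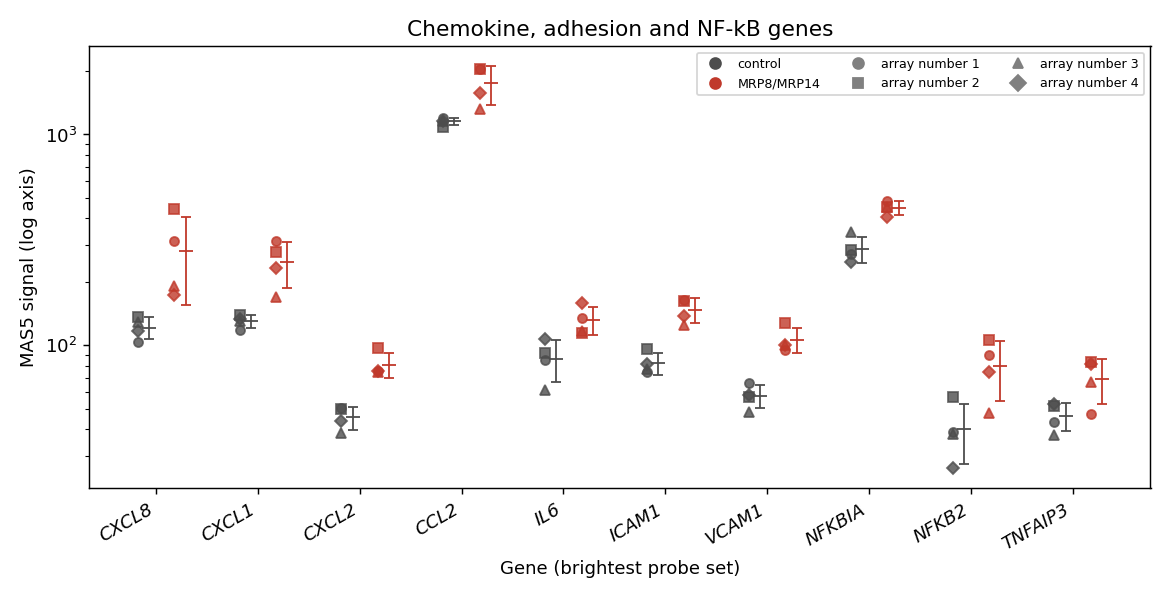
MAS5 signal on a log axis of 10 chemokine, adhesion and NF-kB genes, with control arrays in grey, MRP8/MRP14 arrays in red, symbols marking the array number, and a bar giving the mean and SD of the 4 arrays beside them. CXCL2 signals averaged 45.5 in controls and 80.8 in stimulated cells, and no gene drawn here passed the threshold over all genes.

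Cytoplasmic ribosomal proteins were the fifth list under 0.05, with 30 of 33 members higher (mean log2 fold change 0.19, camera adjusted p = 7.2e-06, but adjusted p = 0.817 with an estimated correlation). RPL29 and RPS9 had log2 fold changes of 0.39 and 0.37 (each adjusted p = 0.417). After quantile normalization the list's mean was 0.0021 (adjusted p = 0.974), and without MRP8/MRP14 replicate 2 it was 0.099. Within the arrays numbered 1 and 2 the mean was 0.34, and within those numbered 3 and 4 it was 0.027.

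The other 25 lists did not pass camera, with adjusted p from 0.0641 to 0.976. Antigen presentation came closest, with 11 of 14 members higher (mean 0.13, adjusted p = 0.0641, and adjusted p = 0.285 with an estimated correlation), including the peptide transporters TAP1 (0.37) and TAP2 (0.77, from a dim probe set at or above the 40th percentile on only 4 arrays, 3 of them stimulated). It passed with the filter at the 60th percentile (adjusted p = 0.0407), with the mean of a gene's probe sets (adjusted p = 0.0386), without MRP8/MRP14 replicate 3 (adjusted p = 0.0459) and with the ACTB ratio as a covariate, chosen after seeing the data (adjusted p = 0.0498). Its mean ranged from 0.067, without MRP8/MRP14 replicate 2, to 0.15 over single arrays left out. Of 20 genes of cholesterol synthesis, 17 were higher (mean 0.13, adjusted p = 0.0972), with 1.16 for MVD, which passed over the list alone with the block but not without it (adjusted p = 0.0493 against adjusted p = 0.435), and 0.27 for SREBF1. The MVD probe set was dim, with a mean control signal of 20.65, and was at or above the 40th percentile on only 5 arrays, 3 of them stimulated. The interferon list had 18 of 28 members higher (mean 0.062, adjusted p = 0.149), with IFITM3 at 0.57 and GBP1 at -0.38, and passed without MRP8/MRP14 replicate 3 (adjusted p = 0.0223), its mean ranging from 0.022 to 0.12 over single arrays left out. Angiogenic and growth factors had a mean of 0.12 (adjusted p = 0.178), or 0.048 without control replicate 4, with DKK1 at -0.32 and GDF15 at 0.27.

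Death and stress lists gave small means. Pro-apoptotic genes had 12 higher and 13 lower members (mean 0.058, adjusted p = 0.588), with BAX at 0.80 and BNIP3L at 0.61. The block passed 3 of them, and none without it, when adjusted over the list alone. Probe sets of BAX ranged from 0.027 to 0.83. Anti-apoptotic genes had a mean of 0.049 (adjusted p = 0.575), with CFLAR passing as lower over the list alone and TNFAIP3 at 0.54. The mean was 0.080 for the unfolded protein response (adjusted p = 0.549, HERPUD1 at -0.19, XBP1 at 0.25) and 0.021 for the amino acid response (adjusted p = 0.803, STC2 at -0.44, SLC3A2 at 0.42). It was -0.035 for heat shock proteins (adjusted p = 0.976, HSPE1 at -0.49, HSP90AB1 at 0.34 but at -0.22 to 0.065 by its other probe sets) and -0.043 for the oxidative stress list (adjusted p = 0.976, NQO1 at -0.35, FTL at 0.32). Hypoxia and glycolysis had a mean of 0.035 (adjusted p = 0.588, KDM3A at -0.53, ENO1 at 0.39), and oxidative phosphorylation had one of -0.062 (adjusted p = 0.912, NDUFB3 at -0.58, SDHD at -0.38). Immediate early genes averaged -0.0022 (adjusted p = 0.976), with IER3 at 0.45. JUNB passed as lower over that list alone (-0.60), but not with the block, and its other probe set differed by 0.95.

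Among proliferation genes, the mitosis list had 16 higher and 15 lower members (mean -0.020, adjusted p = 0.976). Its KIF23 (-0.64) and MAD2L1 (-0.68), which act in cytokinesis and in the spindle checkpoint, passed as lower when adjusted over the list alone. DNA replication averaged 0.069 (adjusted p = 0.588), with CDT1 at 0.62 and POLE2 at -0.57. The p53 and cell cycle inhibitor list averaged 0.0055 (adjusted p = 0.976), with CDKN1B at -0.49.

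Endothelial identity genes averaged 0.049 (adjusted p = 0.976), with the VEGF receptor KDR at -0.47 and EPAS1 at 0.58. Leaving out single arrays moved both: EPAS1 was at 0.044 without control replicate 4, and KDR went from -0.73 without control replicate 3 to -0.24 without control replicate 2. A dimmer probe set of each had the other sign (-0.31 for EPAS1 and 0.092 for KDR). Junction proteins averaged -0.026 (adjusted p = 0.976), with CTNND1 at -0.45 (-0.27 without control replicate 3) and GJA1 at -0.24 (0.57 by its dimmer probe set), and the cytoskeleton and focal adhesion list averaged -0.0019 (adjusted p = 0.976). In that list ITGAV (-0.72), the alpha chain of vitronectin-binding integrins, passed as lower over the list alone but not with the block, and its other probe sets differed by 0.22 and -0.41. CALD1 was at -0.42. Coagulation and fibrinolysis averaged -0.0034 (adjusted p = 0.976), with PLAT at -0.45 and THBS1 at 0.77, which was 0.38 without control replicate 4. Other THBS1 probe sets differed by 0.78 and -0.13. Extracellular matrix genes averaged 0.042 (adjusted p = 0.549), with LAMA4 at -0.49 and COL5A2 at 0.25. Mean, median and test direction differed in sign in some of these lists: junctions, cytoskeleton, coagulation, pro-apoptotic genes, oxidative stress, heat shock, immediate early genes, mitosis and p53 targets. Camera compares a list with the other genes, whose median was -0.025.

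For the stimulus and its receptors, the S100 list averaged 0.021 (adjusted p = 0.976), with S100A4 at 0.63 (-0.024 by its other probe set) and LY96, the TLR4 co-receptor also called MD-2, at -0.50. S100A4 passed over the list alone with the block but not without it (adjusted p = 0.0170 against adjusted p = 0.260). S100A8 and S100A9 stayed under the 40th percentile on all 8 arrays and were not tested. Their signals were 12.5 ± 2.6 and 1.6 ± 1.3 in controls and 7.4 ± 4.1 and 2.1 ± 0.67 in stimulated cells (SD, n = 4 per group). AGER, the receptor RAGE, measured 24.6 ± 6.6 and 26.3 ± 1.4 (SD, n = 4 per group; log2 fold change 0.13, adjusted p = 0.830). TLR4, also named by the rule, was not among the 5517 genes tested, so no value is given for it.

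Lists of markers of other cell types did not pass camera. Leukocyte markers averaged -0.095 over 7 genes (adjusted p = 0.976), with ITGAX at -0.78, NKG7 at 0.38, CXCR2 at -0.14, CD3E at -0.20 and LAPTM5 at 0.26. Over single arrays left out these ranged widely, with ITGAX from -1.19 to -0.53, CXCR2 from -0.28 to -0.027, CD3E from -0.32 to -0.083 and LAPTM5 from 0.019 to 0.41. Epithelial markers averaged 0.030 over 7 genes (adjusted p = 0.803), with KRT18 at 0.036, KRT7 at -0.19, KRT8 at 0.23 and MUC1 at 0.27. Without 1 array KRT18 ranged from -0.053 to 0.14, KRT7 from -0.32 to -0.068 and MUC1 from 0.16 to 0.35, and MUC1 probe sets ranged from -0.68 to 0.84. Fibroblast and mural markers averaged 0.041 over 13 genes (adjusted p = 0.976), with MYH11 lower as above, TAGLN at 0.094 and NOTCH3 at 0.025. With the block, fry called that list in the lower direction (adjusted p = 0.0139, against adjusted p = 0.876 without it), although its mean was above 0. Of its members 7 were higher and 6 lower, and MYH11, limited as above, was the only 1 to pass over the list alone with the block. COL1A1 was at 1.57 with an SE of 1.07, and its signal was 26.2 in control replicate 4 against 995 to 1384 in the other controls. Without that array COL1A1 was at 0.23.

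**Figure D3:**
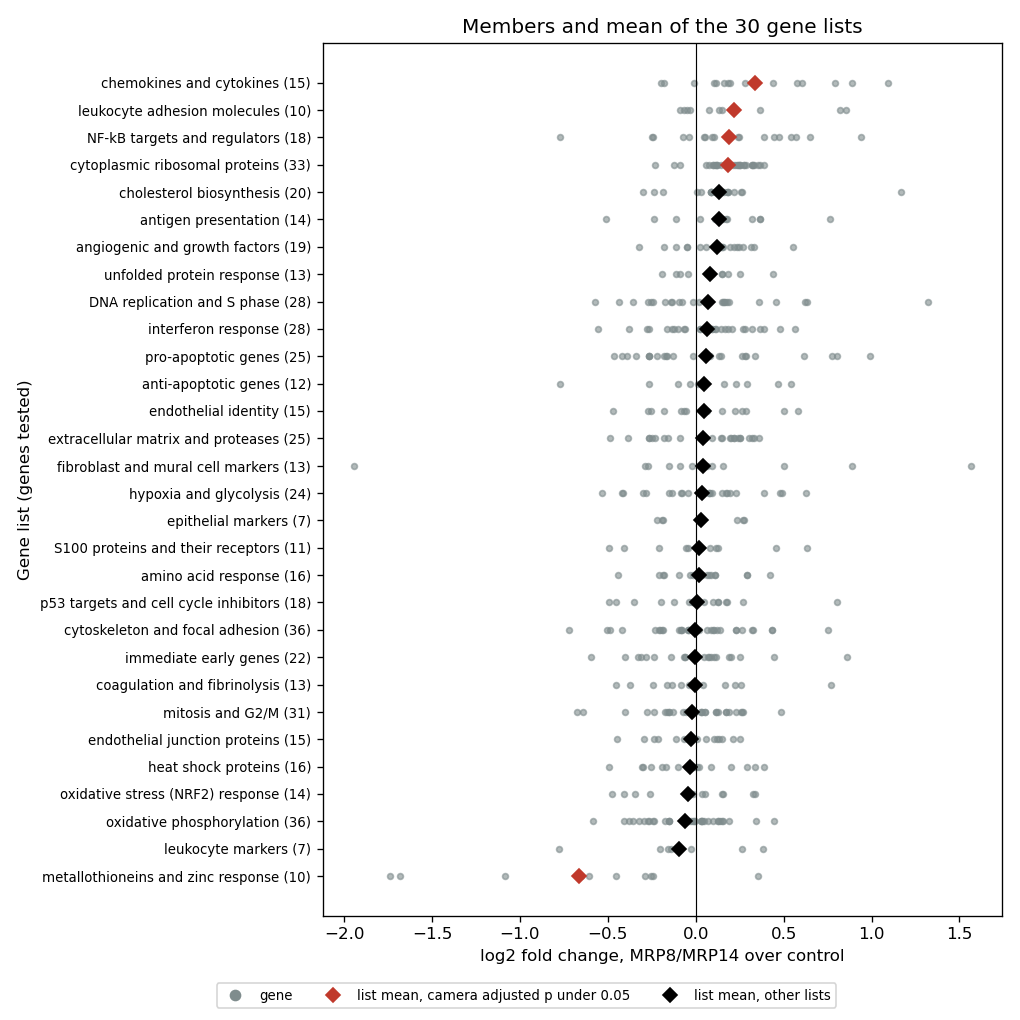
Log2 fold change, MRP8/MRP14 over control, of the tested members (grey points) and the mean (diamonds) of each of the 30 gene lists, with the number of genes tested in brackets. Red diamonds mark the 5 lists under an adjusted p of 0.05 by camera with the preset correlation. The metallothionein and zinc mean lies at -0.67, and the chemokine and cytokine mean lies at 0.34.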

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

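The tests on SLC30A1 and HMOX1, the comparison by probe set suffix and the count of splits at an unadjusted p were chosen after the results were seen. Single arrays were compared with the other 3 of their group in 170 groups, where chance flags about 1 in 20, or 8.5, and 11 stood far from the others. Of these, 6 were in control replicate 4. On that array COL1A1 was 26.2 (others 995 to 1384), AGER 14.7 (27.2 to 28.3) and SDHD 345.9 (290.3 to 297.1). Its ACTB and TFRC ratios of 3 prime to 5 prime signal were 2.03 (1.004 to 1.13) and 2.61 (1.70 to 1.81), and its mean correlation with the other arrays was 0.953 (0.962 to 0.964). Elsewhere, CXCL2 was 97.5 in MRP8/MRP14 replicate 2 (74.5 to 75.7), JUNB 119.9 in MRP8/MRP14 replicate 4 (95.1 to 98.8) and MT1B 493.2 in MRP8/MRP14 replicate 3 (654.1 to 676.4). NKG7 was 42.0 in control replicate 2 (25.1 to 27.3) and XBP1 724.0 in control replicate 1 (561.4 to 562.4).

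Of the 10 tested members of the zinc list, SLC30A1, MT1X and MT1E passed as lower over all genes. With the replicate block MT1E (adjusted p = 0.137) and MT1X (adjusted p = 0.222) did not pass, and leaving out any single array ended each of these calls. The list's call ended among plain probe sets (adjusted p = 0.129), where the mean over 6 members was -0.53. SLC30A1 and MT1X still passed there over all genes (each adjusted p = 0.0387), while MT3 and SLC39A14 were higher. The list's call also ended with the block and an estimated correlation together (adjusted p = 0.450). In that setting 0 lists passed and few degrees of freedom remain, so it can hardly keep any call and decides little. With the block at the preset correlation the list passed (camera adjusted p = 4.6e-05, mean -0.67). SLC30A1, no copy of the metallothioneins, was at -1.68, but it is one of the genes that made the pattern. Its fall was known when the test was chosen, so it cannot test cross-hybridisation among metallothionein copies. Nor does it speak to their own values. Control replicate 4 as the whole cause is argued against by a list mean of -0.67 without it. Less glucocorticoid drive was expected to give a median of -0.5 or lower over glucocorticoid targets. The 12 measured of 18 targets had a median of -0.023 (quartiles -0.20 and 0.22), which argues against a shared fall. Single targets went both ways, from -0.41 for GLUL to 0.41 for TSC22D3. Some, such as DUSP1 and CEBPB, also belong to other lists tested here, so a smaller loss of drive is not excluded. Less zinc available to cells that received a zinc-binding protein complex stays open as a hypothesis: HMOX1, which other metals and oxidants raise, was at -0.48 with an SE of 0.46, too wide to decide. No zinc was measured and no group changed zinc alone, so less available zinc may or may not be the cause.

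Lower genes outnumbered higher ones at an unadjusted p under 0.05, at 68.4%. Control replicate 4 and the kind of probe set are argued against, since the share was 71.0% without that array and 69.9% among plain probe sets. The scaling of the arrays to a common trimmed mean may account for part of it: the share was 62.8% after quantile normalization, between the bounds set beforehand, and 57.3% after median centring. Median log2 fold changes went from -0.11 in the lowest of 10 equal classes of signal to 0.093 in the highest, and from -0.064 to 0.018 after quantile normalization. Scaling and a wider response to MRP8/MRP14 cannot be told apart here, because no measure outside the arrays fixes the scale.

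Chemokine, adhesion and NF-kB lists averaged higher by camera at the preset correlation, but none of the 3 calls held with an estimated correlation (adjusted p = 0.135, 0.691 and 0.135) or with fry in one direction (adjusted p = 0.0901, 0.421 and 0.0901), though with the block fry called the adhesion list (adjusted p = 0.0223). Control replicate 4 as the whole cause is argued against by the smallest of the 3 means without it, 0.17, and scaling by the smallest after quantile normalization, 0.22, both above the 0.15 set beforehand. A response to MRP8/MRP14 stays a hypothesis, because without the block none of the calls, on lists fixed beforehand, held in the other directional set tests. The controls were untreated and no other group was measured, so the proteins and anything else added with them cannot be told apart. The estimated correlations were 0.065, 0.30 and 0.0031. That of the NF-kB list lies under the preset 0.01, so a higher correlation is not why its call ended. The estimated setting also has far fewer degrees of freedom. At an estimated correlation of -0.020, the zinc list's unadjusted camera p went from 9.8e-08 to 0.0014. Calls that ended there therefore do not show that correlation between members made them. Fry without regard to direction called each of the 3 (adjusted p = 0.0054, 0.00028 and 0.00018), but it tests for change in either direction and not for a shared rise.

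Other splits of the 8 arrays into 4 and 4 did not allow chance to be excluded for the counts. Of 35 splits, the real one included in each count, 2 gave as many genes as the real one (4, highest other 40), 2 as many genes changed at least 2-fold (4, highest other 13) 8 as many lists (5, highest other 8) and 4 as many genes at an unadjusted p under 0.05 (579, highest other 940). The split with 40 and 940 genes set the arrays numbered 1 and 2 against those numbered 3 and 4, which points to a difference between these arrays. The labels do not say what that difference is. With that division as a block, chosen after seeing the data, 3 genes passed. Among the 8 splits that part all 4 pairs, the highest of the others gave 1 gene, 4 lists and 266 genes at an unadjusted p under 0.05. These 8 are too few for a share under 0.05.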

How the results depend on the processing

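The alternatives with both arrays numbered 4 left out, with the ACTB ratio as a covariate, with plain probe sets and with the numbers 1 and 2 against 3 and 4 as a block were chosen after seeing the data. The count of 4 genes, all lower and all changed at least 2-fold, was 4 with quantile normalization, without the offset, with the larger offset and with the mean of a gene's probe sets. It was 3 with median centring, the stricter filter, the intensity trend, plain probe sets and that block of numbers. With the replicate block it was 2, at either fold limit, and with the ACTB covariate it was 2. It was 0 with no filter, where more and dimmer genes were tested, and 0 with the replicate block and both arrays numbered 4 left out, where 705 genes had an unadjusted p under 0.05. Leaving out 1 array gave 0 to 1, with fewer arrays in each fit. The count of 5 lists was 1 with an estimated correlation, 1 with fry and 3 among plain probe sets, where the zinc and adhesion calls ended and fewer members were tested, and 4 to 7 without 1 array. The replicate block left the same 5 lists by camera, moved fry's count from 1 to 3, adding adhesion molecules and fibroblast and mural markers, and the estimated-correlation count from 1 to 0. Adjusted over the list alone, it also moved chemokines and cytokines from 5 to 6, and passed MVD and S100A4. Apart from MT1E, MT1X and the calls printed beside it in the results, the replicate block changed no other call. Differences in the ACTB and GAPDH ratios ranged over single arrays left out from -0.36 to -0.024 and from -0.11 to 0.042. Each stayed within 1 SD of the value from all arrays, by the SD of the 8 arrays around their group means (0.31 and 0.15), though not always by that of the stimulated arrays alone (0.094 and 0.087).

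Of the log2 fold changes of named genes, 1571 kept their direction and side of the threshold over the alternatives, 38 lost the call and 18 turned sign. Of list shifts, 535 kept both, 8 lost and 5 gained a call, and 81 turned direction relative to other genes, over 13 lists, with 0 past the threshold in either fit. The cause of these turns was not tested, and the values follow. With the replicate block, fibroblast and mural markers 0.041, and likewise 0.041 with the numbers 1 and 2 against 3 and 4 as a block, with coagulation -0.0034 and leukocyte markers -0.095. With the replicate block and both arrays numbered 4 left out, AGER was -0.080, coagulation -0.058, immediate early genes -0.071, oxidative phosphorylation 0.014 and endothelial identity -0.074. With the ACTB covariate, AGER was -0.085, EPAS1 -0.0072, KRT18 -0.039, junctions -0.065, coagulation -0.064, heat shock -0.079, immediate early genes -0.063, oxidative phosphorylation -0.0061 and endothelial identity -0.13. With quantile normalization, KRT18 was -0.13, junctions -0.021, cytoskeleton -0.057, coagulation 0.00088, oxidative stress -0.064, heat shock -0.062, immediate early genes -0.00066, mitosis -0.020 and leukocyte markers -0.050. With median centring, junctions were 0.0078 and fibroblast and mural markers 0.074, and the latter were 0.010 with no offset. With no filter, junctions were -0.086, coagulation -0.049, mitosis -0.020, leukocyte markers 0.013 and fibroblast and mural markers 0.015. With the filter at the 60th percentile, cytoskeleton was -0.0016, coagulation -0.0022, immediate early genes -0.0029 and mitosis -0.022. With the mean of a gene's probe sets, GJA1 was 0.17, JUNB 0.18, MT3 0.081, junctions -0.041, heat shock -0.083, mitosis -0.054 and leukocyte markers -0.053. With plain probe sets, MT3 was 0.41, cytoskeleton -0.047, coagulation -0.015, heat shock -0.098, immediate early genes -0.012, the S100 list -0.040, leukocyte markers -0.011 and fibroblast and mural markers -0.091. Over the arrays left out one at a time, log2 fold changes ranged from -0.11 to 0.26 for NOTCH3, from -0.076 to 0.20 for AGER and from -0.053 to 0.14 for KRT18. List means ranged from -0.060 to 0.066 for p53 targets, -0.16 to 0.060 for leukocyte markers, -0.066 to 0.044 for oxidative stress, -0.058 to -0.00051 for heat shock, -0.045 to 0.017 for mitosis and -0.066 to 0.019 for junctions. They ranged from -0.029 to 0.029 for cytoskeleton, -0.060 to 0.065 for immediate early genes, -0.12 to 0.22 for endothelial identity, -0.067 to 0.042 for coagulation, -0.099 to -0.0085 for oxidative phosphorylation, -0.028 to 0.063 for the S100 list and -0.026 to 0.31 for fibroblast and mural markers. Other list means that moved by over 1.5 times ranged from -0.0086 to 0.044 for the amino acid response, -0.010 to 0.10 for anti-apoptotic and 0.0057 to 0.089 for pro-apoptotic genes, -0.0028 to 0.062 for epithelial markers, 0.0094 to 0.063 for extracellular matrix, 0.010 to 0.074 for hypoxia and glycolysis and 0.024 to 0.14 for the unfolded protein response. Leaving out 1 array moved 22 of 79 named genes by over 1.5 times or across 0, and 0 of these were past the threshold. Beside those given elsewhere, these ranged from -0.38 to -0.16 for MT2A, -0.41 to -0.14 for MT3, -0.44 to -0.14 for MTF1, 0.15 to 0.39 for GDF15, -0.29 to -0.12 for HERPUD1, 0.14 to 0.34 for XBP1, 0.28 to 0.53 for SLC3A2 and 0.042 to 0.15 for TAGLN. Signals near the floor limit dim genes such as MYH11.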

Other observations

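Signals on the 4 arrays numbered 1 and 2 did not overlap those on the 4 arrays numbered 3 and 4 for 641 of 5517 genes, 11.6%. Chance gives 2.86% for a split fixed beforehand, which this one was not, so that share is no fair measure for it. For treatment, the genes whose signals did not overlap were 126 higher and 271 lower. Of the 641, 232 were higher and 409 lower on the arrays numbered 1 and 2. This division was looked at because it gave the most genes past the threshold of all splits, the genes below were chosen after their values were seen, and no explanation was tested.

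Of the 15 tested endothelial identity genes, 7 were higher on all 4 arrays numbered 1 and 2, 1 was lower and the others, among them KDR, NOS3 and ERG, overlapped. In this list 53.3% of genes did not overlap, against 11.6% of all genes, and no enrichment test was run. CDH5, the cadherin of endothelial junctions, measured 294 to 357 on the arrays numbered 1 and 2 and 161 to 204 on the others. PECAM1 measured 163 to 201 and 97.3 to 116, and ENG, the co-receptor endoglin, 625 to 869 and 338 to 470. Outside that list, CD34 measured 274 to 382 and 147 to 192, and RNASE1 212 to 270 and 80.5 to 121. Of 13 genes of the unfolded protein response, 4 were higher on the arrays numbered 1 and 2, among them the chaperone HSPA5, at 916 to 1010 and 500 to 613. In the other direction, 5 of 18 p53 and cell cycle inhibitor genes were lower there, with CDKN1A at 394 to 531 and 722 to 963. The smooth muscle actin ACTA2 measured 41.8 to 48.8 and 93.4 to 140.5, and the adhesion receptor CXADR 17.0 to 42.0 and 89.5 to 140.5.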
